A study of Mus musculus with 230 samples.

How the data were processed

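RNA was measured in tissue from 6 brain regions of male C57BL/6J mice that had self-administered cocaine or saline. The regions were the basolateral amygdala (BLA), the dorsal striatum (CPu), the nucleus accumbens (NAc), the prefrontal cortex (PFC), the ventral hippocampus (vHipp) and the ventral tegmental area (VTA). Mice were killed after 24 h of withdrawal without a further injection (S24 after saline, C24 after cocaine), or 1 h after a saline or cocaine injection given at 30 d of withdrawal. These last groups carry 2 letters, the first for the self-administered solution and the second for the injection (SS, SC, CS and CC). The number in each library's title was taken as the mouse, since every number occurred under 1 condition, in 4 to 6 regions, and there were 45 numbers for 230 libraries.

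Per the labels' protocols, RNA was extracted with a column kit after Trizol, treated with DNase, depleted of ribosomal RNA and made into libraries with a ScriptSeq Complete Gold kit; the molecule field of the same labels reads polyA RNA, which is a different selection. The deposited values are raw counts of reads per Ensembl mouse gene, in a single table with 1 column per library. Per the submitters' processing notes, HTSeq and limma were used with the build mm10. The aligner, the annotation release, the strand setting of the counting and any filter on reads are not stated. The values were checked to be whole numbers of 0 or more with no identical columns. Of the 43346 gene identifiers, 42462 (98.0%) had a symbol in GENCODE M21, which also gave chromosomes and positions, and 9117 had no count in any library. The genes of the mitochondrial chromosome were listed with a count of 0 in every library.

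The total count per library ran from 11866570 to 42135683 reads, with a mean of 23614576. The standard errors given come from the edgeR and limma fits to libraries. In the 6-region fit they rest on the consensus correlation between libraries of a mouse, and those of 1 mean per mouse were larger for Gbp4 (0.43 against 0.24), Tnfsf10 (0.21 against 0.12), Osmr (0.21 against 0.11) and Adamts1 (0.16 against 0.099).

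The comparisons, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The 6 planned contrasts were C24 against S24, CS against SS, SC against SS, CC against SS, CC against CS, and the interaction, which is the difference between the effect of a cocaine injection after cocaine (CC against CS) and after saline (SC against SS). Each region was fitted on its own with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr at a minimum count of 10 and a minimum total of 15, libraries were scaled by TMM, and contrasts were tested with the robust quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method over the genes of a region and contrast, with a threshold of 0.05. CPM values in the text were scaled with TMM factors, from the libraries of the region for the regional contrasts and from all libraries elsewhere.

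Changes common to the regions were tested with limma 3.58.1 on voom weights for all 230 libraries. The model held the 36 region and condition groups, and the mouse was a block through duplicateCorrelation. Each contrast was averaged over the 6 regions with equal weight. A moderated F test asked whether the 6 regional effects of a gene differed. The fit without the block, DESeq2 size factors, no filter on low counts and sample quality weights were the alternatives. The pairing by mouse was checked on deviations from the group means over 15749 genes. Libraries with the same number from different regions had a median correlation across genes of 0.09 over 486 pairs, of which 225 lay above 0.1. Libraries with different numbers of the same condition had a median of -0.013 over 3228 pairs. The consensus correlation between libraries of a mouse was 0.040, while the genes called in C24 against S24 had a median correlation of 0.335 of their own and Gbp4 of 0.912, so the errors of such genes are understated by the block.

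The 24 gene lists were tested in each region with camera at a preset correlation between genes of 0.01, adjusted over the 144 list and region tests of a contrast. The same test with an estimated correlation and fry stood beside it. For the fixed lists, the members were also adjusted over the list alone. Fold changes were correlated across genes only between contrasts that shared no library.

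Alternatives for the regional counts were DESeq2 1.42.0, limma voom, no filter on low counts, 2 surrogate variables from sva 3.50.0 and, in groups of up to 5 libraries, the removal of each library in turn. Added after the data were seen were a limma fit to 1 mean per mouse (log2 CPM centred within each region and averaged over the mouse's regions), an exact 2-sided permutation of a list's mean per library, the 6-region fit and the list scores without each mouse, all fits without the libraries that stood apart from their group in total count, in the share of pseudogene counts, in ribosomal protein genes or in genes of other regions and tissues (Dixon's test at the 95% level), all fits without the libraries carrying more than 1 CPM of Gm20594, and the contrast of SS against S24. Sharing of sequence between named genes and other genes was measured as the share of a transcript's 31-base words found in another gene.

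The gene names in the text follow the rule fixed beforehand. It takes, per region, the 3 called genes with the smallest adjusted p after predicted genes and pseudogenes were set aside. From the 6-region fit it takes the first 5 called genes, and from each list up to 3 called members. Where no region had a call it takes the gene with the smallest p in each region, as values only. Fos, Arc, Egr1, Npas4 and Fkbp5 are always given for the contrasts with an injection. Other genes named in the text were chosen after their values were seen.

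The edgeR fits of 3 regions, the 6-region fit and the fit to mouse means were tested on simulated counts with 200 changed genes drawn from the real means and library sizes. The other regions and contrasts were not simulated. Changed genes were taken only above a set mean count, and genes were drawn independently with no tissue from other regions. The 6-region simulation gave every gene the same dispersion and the same size of mouse effect. It held 3000 genes, 200 of them changed, against 18927 genes tested in the real fit. So large a changed share makes the adjusted threshold easier to pass, and the 6-region shares may be too high for the real fit. The shares below thus do not cover genes of low count or genes that vary widely between mice. In a simulated SC against SS contrast of the NAc (5 and 6 libraries, 16809 genes), 42%, 70%, 96% and 100% of genes changed by 1.3, 1.5, 2 and 3 times were called. For the VTA (5 and 6 libraries, 16987 genes) the shares were 72%, 90%, 100% and 98%, and for the PFC (7 and 7 libraries, 16828 genes) 66%, 88%, 98% and 100%. The 6-region fit (37 and 39 libraries, 3000 genes) called 28%, 86%, 98% and 100% of the genes changed by 1.15, 1.3, 1.5 and 2 times, and the fit to mouse means 24%, 90%, 100% and 100%. All 230 libraries were used and no column of the table was left out.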

Results

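The data comprised 230 RNA sequencing libraries from 6 regions of the reward circuitry of 45 male mice, each mouse in 1 of 6 conditions. Tissue was taken 24 h into withdrawal from saline (S24, 8 mice) or cocaine (C24, 8 mice) self-administration, or at 30 d of withdrawal, 1 h after an injection. In the later conditions saline mice received saline (SS, 8 mice) or cocaine (SC, 8 mice), and cocaine mice received saline (CS, 6 mice) or cocaine (CC, 7 mice). In the order S24, C24, SS, SC, CS and CC, the basolateral amygdala (BLA) had 7, 6, 7, 7, 5 and 6 libraries, and the dorsal striatum (CPu) had 8, 8, 7, 6, 6 and 7. The nucleus accumbens (NAc) had 8, 8, 6, 5, 5 and 7, and the prefrontal cortex (PFC) had 7, 8, 7, 7, 5 and 7. The ventral hippocampus (vHipp) had 7, 8, 6, 7, 6 and 5, and the ventral tegmental area (VTA) had 6, 6, 6, 5, 3 and 5. Library totals ran from 11866570 to 30246933 counts in the BLA and from 15981104 to 33037225 in the CPu. They ran from 16258641 to 42135683 in the NAc, from 16716512 to 35054336 in the PFC, from 17159879 to 28746378 in the vHipp and from 19570662 to 32520635 in the VTA.

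The libraries carried transcripts of the regions on their labels. Drd1, a dopamine receptor gene of striatal projection neurons, reached 415 ± 31.6 CPM (SD, n = 42) in the CPu and 256 ± 38.7 CPM (n = 39) in the NAc, against 30.0 ± 12.8 CPM (n = 41) in the PFC. Drd2 reached 227 ± 23.1 CPM in the CPu and 114 ± 20.7 CPM in the NAc, and Ppp1r1b, which encodes the striatal phosphoprotein DARPP-32, reached 1096 ± 240 CPM in the NAc. The dopamine transporter gene Slc6a3 reached 1595 ± 503 CPM (n = 31) in the VTA, where Drd2 had 83.5 ± 23.5 CPM. Prox1, a marker of dentate granule cells, had 89.4 ± 64.2 CPM (n = 39) in the vHipp. Single vHipp libraries ran from 9.84 to 216 CPM, and the lowest lay below the VTA mean of 32.1 CPM. The vesicular glutamate transporter gene Slc17a7 reached 1509 ± 242 CPM in the PFC, 1394 ± 306 CPM in the vHipp and 811 ± 293 CPM (n = 38) in the BLA. Rspo2 reached 28.0 ± 8.61 CPM in the BLA, 35.1 ± 8.52 CPM in the PFC and 27.3 ± 9.98 CPM in the vHipp, against 0.541 ± 0.735 CPM in the CPu, and so did not mark the BLA alone. Single libraries carried transcripts of other regions, with up to 62.0 CPM of Slc6a3 in the NAc and up to 160 CPM in the vHipp.

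**Figure D1:**
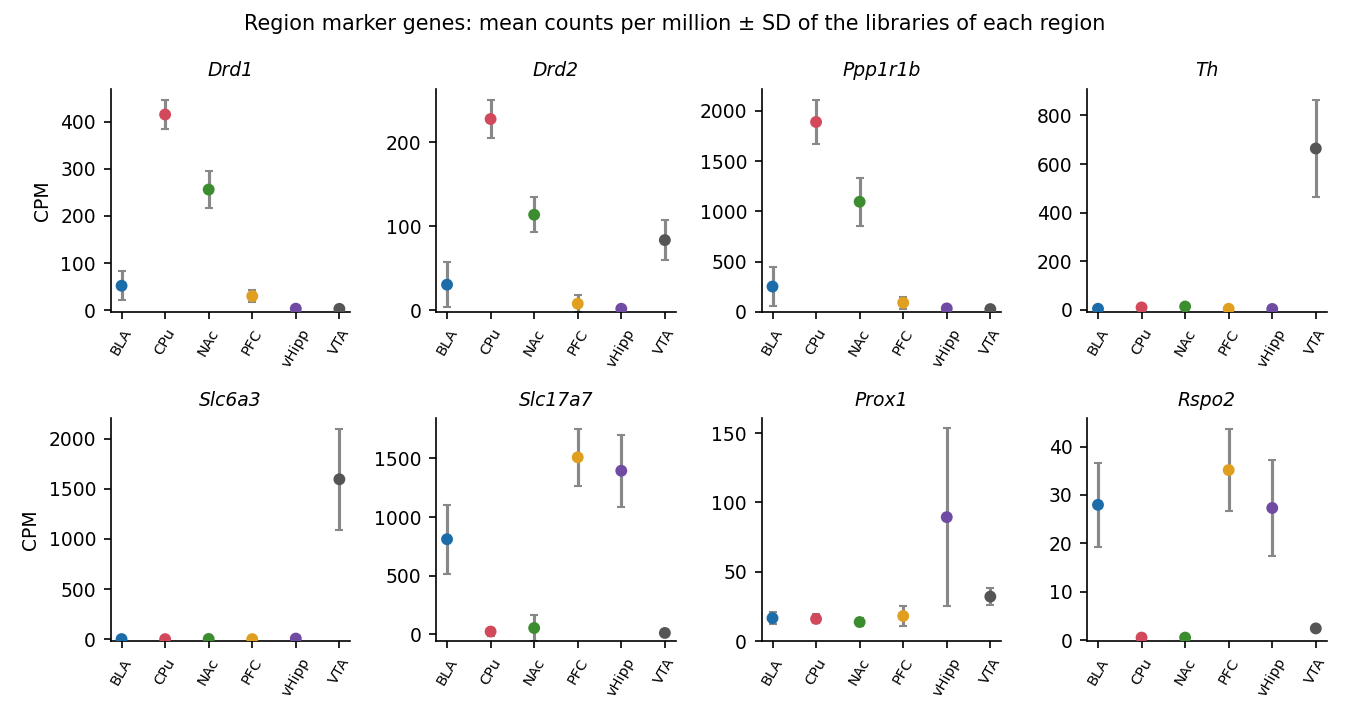
Mean level of 8 marker genes in each region, in CPM on a linear axis, with 1 panel per gene; points are means and error bars the SD over the libraries of a region. Drd1 averaged 415 CPM in the CPu and Slc6a3 averaged 1595 CPM in the VTA.

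The first comparison asked how gene expression differed 24 h after the end of self-administration between cocaine and saline mice (C24 against S24). Over the 6 regions together, 155 genes rose and 6 fell in C24 in the limma fit. Tnfsf10, which encodes the death ligand TRAIL (mm10 chromosome 3, 27317028 to 27342427), rose by a log2 fold change of 0.94 (SE 0.12, adjusted p = 6.47e-09) and was higher in 6 of 6 regions. Its level was 4.87 ± 2.27 CPM in C24 and 2.46 ± 0.945 CPM in S24 (SD over 8 mice each). Guanylate-binding protein genes, which interferons induce, rose with it. Gbp4 (chromosome 5, 105115767 to 105139586) rose by 1.76 (SE 0.24, adjusted p = 2.45e-08), from 2.33 ± 1.94 CPM in S24 to 10.4 ± 10.4 CPM in C24, and Gbp2, Gbp3 and Gbp9 rose by 1.13, 0.91 and 0.71, each in 6 of 6 regions. In the VTA alone, edgeR called Gbp9, with 5.36 ± 1.80 CPM in C24 and 2.94 ± 0.404 CPM in S24 (n = 6 each, log2 fold change 0.87, SE 0.15, adjusted p = 0.0466), and 6 of 6 C24 libraries lay above the S24 mean.

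Among families chosen after these genes were seen, 7 of the 8 Gbp genes tested rose. No test is given, since the families were picked from the called genes. Gbp9 and Gbp4 share 18.29% and 14.95% of their sequence with other genes, most with Gbp8 and Gbp6, so the Gbp genes may not count separately. All 7 tested immunity-related GTPase genes, which act in defence against intracellular pathogens, rose as well (Irgm1, Irgm2, Igtp, Iigp1, Tgtp1, Tgtp2 and Ifi47). Of 18 class I histocompatibility genes, which present antigen, 6 rose (H2-D1, H2-K1, H2-Q4, H2-Q5, H2-Q6 and H2-Q7); H2-Q6 and H2-Q7 share 51.8% and 39.2% of their sequence with other genes and are uncertain. Mice differed widely: Gbp4 ran from 1.63 to 27.6 CPM among the 8 C24 mice and from 0.919 to 6.82 CPM among the 8 S24 mice. Mouse-203, mouse-223 and mouse-194 of C24 had 16.0, 27.6 and 23.7 CPM of Gbp4 and 7.4, 8.0 and 7.2 CPM of Tnfsf10. The other C24 mice had 1.63 to 4.92 CPM of Gbp4 and 2.37 to 3.90 CPM of Tnfsf10. These lay within the S24 ranges, which for Tnfsf10 ran from 1.43 to 4.07 CPM. With 1 mean per mouse, limma called 0 genes (1328 at an unadjusted p under 0.05), with an adjusted p of 0.212 for Tnfsf10 and 0.416 for Gbp4, whose SE was then 0.43. The count of called genes was 51 without mouse-203, 69 without mouse-223, 83 without mouse-185 or mouse-204, 100 without mouse-201, 106 without mouse-205 and 270 without mouse-195. A difference between regions was called for 0 genes by the limma F test (361 at an unadjusted p under 0.05).

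**Figure D2:**
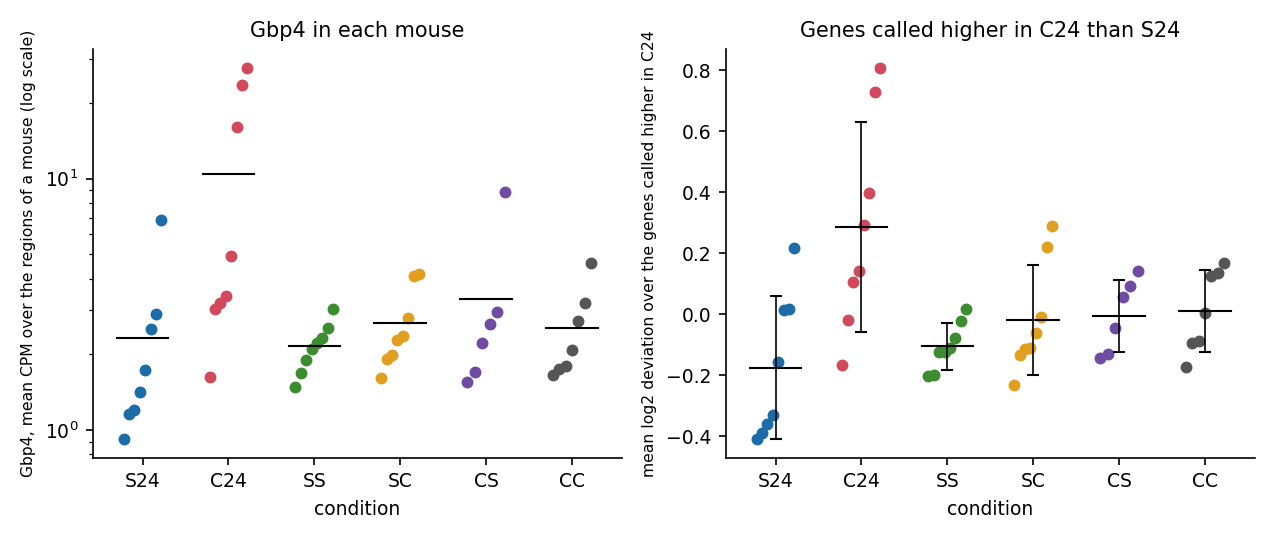
Gbp4 as mean CPM over the regions of a mouse (left, log axis) and the mean log2 deviation over the 155 genes that rose in C24 (right), by condition; points are mice, horizontal lines means, and error bars on the right the SD. For Gbp4 the 8 C24 mice spread from 1.63 to 27.6 CPM and the 8 S24 mice from 0.919 to 6.82 CPM.

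Apart from Gbp9 in the VTA, edgeR called 0 genes in single regions in C24 against S24, with up to 1388 genes at an unadjusted p under 0.05, in the PFC. DESeq2 called 7 in the PFC, 1 in the NAc and 1 in the VTA, and limma voom 0 in each region. Among the fixed lists, camera at the preset correlation called 30 list and region pairs higher and 37 lower. In other random splits of these mice into groups of the same sizes it called a median of 47 pairs. Endothelial and pericyte markers were higher in 5 regions, with a median log2 fold change of 0.32 in the vHipp, and lower in the BLA, with -0.11. In the NAc and the PFC 6 members each, Pecam1 and Pdgfrb in both, passed when adjusted over the list alone, against 0 over all genes (smallest adjusted p = 0.152 with an estimated correlation, in the NAc). Microglia markers were higher in 5 regions, with medians of 0.29 in the vHipp and 0.16 in the NAc. Csf1r, a receptor gene microglia need to survive, passed adjusted over the list alone in both, and Cx3cr1 in the vHipp (adjusted p = 0.265 in the vHipp and 0.275 in the NAc with an estimated correlation). Other tissue markers moved as well. Leptomeningeal fibroblast markers were higher in 3 regions and lower in 1, with medians from -0.51 to 1.07 over the 6 regions (smallest adjusted p = 0.275 with an estimated correlation). Astrocyte markers were higher in 3 regions and lower in 1, with medians from -0.11 to 0.12 (0.451). Choroid plexus and ependymal markers were lower in the vHipp by a median of -4.36, with 8 members adjusted over the list alone, and by -0.47 without the libraries that stood apart, and higher in the PFC by 1.48 (adjusted p = 0.535 and 0.584 with an estimated correlation). Oligodendrocyte markers were higher in the PFC by 0.97 (adjusted p = 0.451 with an estimated correlation) and in the NAc by 0.17 (0.457), and lower in the vHipp by -0.28 (0.715) and the VTA by -0.07 (0.628). Oligodendrocyte precursor markers were higher in 4 regions, by 0.22 in the PFC, and general neuron markers lower in 3, by -0.14 in the vHipp (adjusted p = 0.451 and 0.479 with an estimated correlation). Blood cell markers were higher in the VTA by a median of 1.77, where 8 of 8 passed adjusted over the list alone (adjusted p = 0.451 with an estimated correlation), and without the VTA libraries that stood apart the median was 0.39. They were also higher in the NAc by 0.32 (adjusted p = 0.577 with an estimated correlation) and in the BLA by 0.23 (0.545). In mouse-203 the mean log2 deviation was 1.43 for blood cell, 0.54 for endothelial and pericyte and 0.20 for microglia markers, and in mouse-223 it was 0.88, 0.33 and 0.23. In mouse-194, which had 23.7 CPM of Gbp4, it was -0.18, 0.06 and -0.06. The blood cell value was 1.45 in mouse-175, with 3.20 CPM of Gbp4, and 0.96 in mouse-185 of S24, with 0.919 CPM. Glucocorticoid-responsive genes were lower in 4 regions, by a median of -0.16 in the CPu (adjusted p = 0.451 with an estimated correlation); the difference of the mean scores was -0.09, or -0.04 without mouse-204 and -0.14 without mouse-182. Heat shock and protein folding genes were lower in 5, by a median of -0.13 in the PFC (adjusted p = 0.535 with an estimated correlation), and by -0.09 there without the libraries that stood apart. Mouse-182 in S24 had a score of -0.17 for them, against -0.61 to -0.49 in the other 7 S24 mice, and without it the difference of the mean scores was -0.03 in place of -0.08. Oxidative phosphorylation subunits were lower in 5 regions, by a median of -0.10 in the PFC (adjusted p = 0.535 with an estimated correlation), and higher in the BLA by 0.07 (0.661). With an estimated correlation, with fry and with exact permutation of list means, 0 pairs were called.

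The lasting effect of cocaine self-administration was read from mice injected with saline at 30 d (CS against SS). Over the 6 regions 7 genes rose and 4 fell in CS in the limma fit. Osmr, the receptor gene for oncostatin M, rose by 0.54 (SE 0.11, adjusted p = 0.00894) and was higher in 6 of 6 regions, with 13.5 ± 5.74 CPM in CS (n = 6 mice) and 8.95 ± 2.04 CPM in SS (n = 8 mice). Mouse-151 and mouse-111 of CS had 21.8 and 19.0 CPM, against 6.86 to 12.3 CPM in the other 4 CS mice, and without mouse-151 Osmr was at 0.38 (adjusted p = 1.00). Serpina3g, a protease inhibitor gene, rose by 1.02 (SE 0.21, adjusted p = 0.00894), and Gvin1, an interferon-induced GTPase gene, by 1.22 (SE 0.24, adjusted p = 0.00794). Both are uncertain, since 28.4% of the sequence of Serpina3g and 99.7% of that of Gvin1 occur in other genes. Gvin1 was also low, with 0.235 ± 0.108 CPM in CS and 0.106 ± 0.0436 CPM in SS, passed the filter in the VTA alone among single regions, and with 1 mean per mouse rose by 0.74 (adjusted p = 0.954). Sypl2 fell by 0.39 (SE 0.086, adjusted p = 0.0223). Mid1, a ubiquitin ligase gene, fell by 0.61 (SE 0.13, adjusted p = 0.00894); it shares 31.1% of its sequence with other genes, and its SS mean of 22.4 ± 12.1 CPM held 1 mouse at 51.3 CPM. With 1 mean per mouse limma called 0 genes (791 at an unadjusted p under 0.05), and 0 without the libraries that stood apart (674). The count of 11 genes was 0 without mouse-122, 3 without mouse-035, 4 without mouse-162, 5 without mouse-151, 6 without mouse-111, 7 without mouse-143, 22 without mouse-073 and 36 without mouse-014.

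No single region had a called gene in CS against SS by edgeR, with 378 to 2519 genes at an unadjusted p under 0.05; DESeq2 called 2 in the VTA and 1 in the CPu, and limma voom 0. The gene with the smallest p was Tmem114 in the BLA (log2 fold change -0.89), Mid1-ps1 in the CPu and the PFC (-2.08 and -2.90), Apobec1 in the NAc (0.78) and Emid1 in the vHipp (-0.65, adjusted p = 0.246). In the VTA it was Hcrt, which encodes the hypothalamic peptide hypocretin (7.37, SE 1.27, adjusted p = 0.0762), with 0.0449 to 45.8 CPM in its 3 CS libraries. Without VTA-072 or without VTA-091, Hcrt and Pmch, a further hypothalamic peptide gene, were called (2 genes). The activity-induced genes Fos, Arc, Egr1 and Npas4 and the stress-responsive gene Fkbp5 averaged 0.17, 0.10, 0.07, 0.11 and 0.09 over the regions, none past the test.

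Camera called 35 list and region pairs higher and 23 lower in CS against SS. In other random splits of these mice it called a median of 45 pairs. Immediate early genes, which neuronal activity induces, were higher in the NAc, where 29 of 30 had positive values (median 0.39, adjusted p = 0.556 with an estimated correlation); without the NAc libraries that stood apart the median was 0.13. Heat shock and protein folding genes were higher in 5 regions, with a median of 0.27 in the NAc, and glucocorticoid-responsive genes in 3, with 0.30 in the BLA (for both adjusted p = 0.556 with an estimated correlation). Heat shock scores were 0.70 in mouse-111 and 0.79 in mouse-151, against 0.14 to 0.39 in the other 4 CS mice, and without mouse-151 the difference of the mean scores was 0.09 in place of 0.16. For glucocorticoid-responsive genes it was 0.07 without mouse-111 in place of 0.13. In the vHipp, 11 of 12 choroid plexus and ependymal markers passed adjusted over the list alone, with a median of 5.63 (adjusted p = 0.723 with an estimated correlation), and without the libraries that stood apart the median was 0.79. Leptomeningeal fibroblast markers were lower there by a median of -1.88, with 9 members adjusted over the list alone (adjusted p = 0.693 with an estimated correlation). Microglia markers were lower in the vHipp and the VTA, by medians of -0.34 and -0.43, and higher in the BLA by 0.17 (adjusted p = 0.643 with an estimated correlation). Of the 43 list members that passed adjusted over the list alone, 38 were in the vHipp, against 0 over all genes.

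The response to a first cocaine injection was measured in mice with a saline history (SC against SS). Over the 6 regions 8 genes rose and 13 fell in SC in the limma fit. Atp5j2, a subunit gene of the mitochondrial ATP synthase, rose by 0.65 (SE 0.098, adjusted p = 1.32e-06), from 38.5 ± 3.70 to 65.4 ± 20.1 CPM (SD over 8 mice each), and was higher in 6 of 6 regions. Cox8a, a cytochrome oxidase subunit gene, rose by 0.33 (SE 0.070, adjusted p = 0.00697), and Tmsb4x, which encodes an actin-binding peptide, by 0.30 (SE 0.066, adjusted p = 0.0148). Ctnnd1 fell by 0.23 (SE 0.045, adjusted p = 0.000863) and Rpl10a by 0.21 (SE 0.047, adjusted p = 0.0223); both are uncertain, with 58.6% and 23.7% of their sequence found in other genes. Most other called genes were pseudogenes or predicted genes. Gm11410, a pseudogene chosen after its values were seen, was called by edgeR in the BLA (log2 fold change 5.30, SE 0.83, adjusted p = 0.00384), the NAc (5.42, adjusted p = 0.0128) and the VTA (5.96, adjusted p = 0.00514). The count of 21 genes was 35 without mouse-065, 34 without mouse-105 and 34 without mouse-122.

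These SC calls followed a division of the libraries, found after the values were seen. Gm20594, a predicted gene, had 1.45 to 3.86 CPM in 21 libraries, 19 of the 37 SC libraries and 2 of the 30 CS libraries, and at most 0.0380 CPM in the other 209. Gm11410 had 7.39 to 54.3 CPM in the same 21 libraries and at most 0.960 CPM elsewhere. Atp5j2 had a median of 80.9 against 36.7 CPM, with ranges that overlapped (54.3 to 101 against 23.0 to 98.2 CPM). Without the 21 libraries, limma called 2 genes over the 6 regions, Hsph1 (log2 fold change -0.36) and Mid1 (-0.76), and the adjusted p of Atp5j2 was 0.898. Hsph1 is a heat shock gene, and mouse-161 of SC was low in that list (below). Mid1 had 1 SS mouse at 51.3 CPM and shares sequence with other genes, as given above; with all libraries it lost its call without mouse-122 or mouse-161 (adjusted p = 0.522 and 1.00). In single regions edgeR then called Kcne2 in the BLA (4.87, adjusted p = 0.0465) and 0 genes elsewhere; choroid plexus and ependymal markers, which stood apart in BLA-125 of SC, had a median of 2.06 in the BLA in that fit. With all libraries, the other regional call was Slc6a3 in the NAc (chromosome 13, 73536747 to 73578672), with 13.0 ± 27.9 CPM in SC (n = 5) and 0.454 ± 0.221 CPM in SS (n = 6, log2 fold change 4.80, SE 0.89, adjusted p = 0.0384). Library NAc-083 held 62.9 CPM, and without it edgeR called 1 gene, Gm11410; without NAc-113 it called Slc6a3 alone, and without VTA-065 it called 2 genes in the VTA, Gm11410 and Atp5j2. In the CPu, PFC and vHipp edgeR called 0 genes, with 305, 378 and 1611 at an unadjusted p under 0.05; DESeq2 called 1, 0 and 1, and limma voom 0.

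Immediate early genes were higher in SC in the NAc, where 30 of 30 had positive values (median 0.33, adjusted p = 0.543 with an estimated correlation), and in the VTA (0.31) and the CPu (0.10, adjusted p = 0.611 in both with an estimated correlation). Averaged over the regions, Fos had a log2 fold change of 0.18, Arc 0.10, Egr1 0.13, Npas4 0.12 and Fkbp5 0.10, none past the test. Heat shock and protein folding genes were lower in 5 regions, by a median of -0.17 in the CPu and the PFC (adjusted p = 0.611 with an estimated correlation); without the CPu libraries that stood apart the CPu median was -0.03. Mouse-161 in SC had a score of -0.44 for them, against 0.06 to 0.38 in the other 7 SC mice, and without it the difference of the mean scores was -0.09 in place of -0.17. Medium spiny neuron genes were higher in the VTA by a median of 0.75, and 9 of them, Drd1 and Ppp1r1b included, passed adjusted over the list alone (adjusted p = 0.611 with an estimated correlation); without the VTA libraries that stood apart the median was 0.05. Dopamine neuron genes were lower in the VTA, by a median of -0.31 with 0 of 15 positive (adjusted p = 0.707 with an estimated correlation), and higher in the NAc by 0.46 (0.611), against 0.01 without the NAc libraries that stood apart, NAc-083 among them. Choroid plexus and ependymal markers were higher in the vHipp by a median of 5.30 (0.766) and in the BLA by 1.51 (0.722); without the libraries that stood apart the medians were 1.75 and 0.06. Camera called 31 pairs higher and 20 lower, and 45 list members passed adjusted over the list alone against 1 over all genes. Without the libraries with Gm20594 counts camera called 22 pairs higher and 23 lower, and 30 of these were also called with all libraries. In other random splits of these mice camera called a median of 44 pairs.

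**Figure D3:**
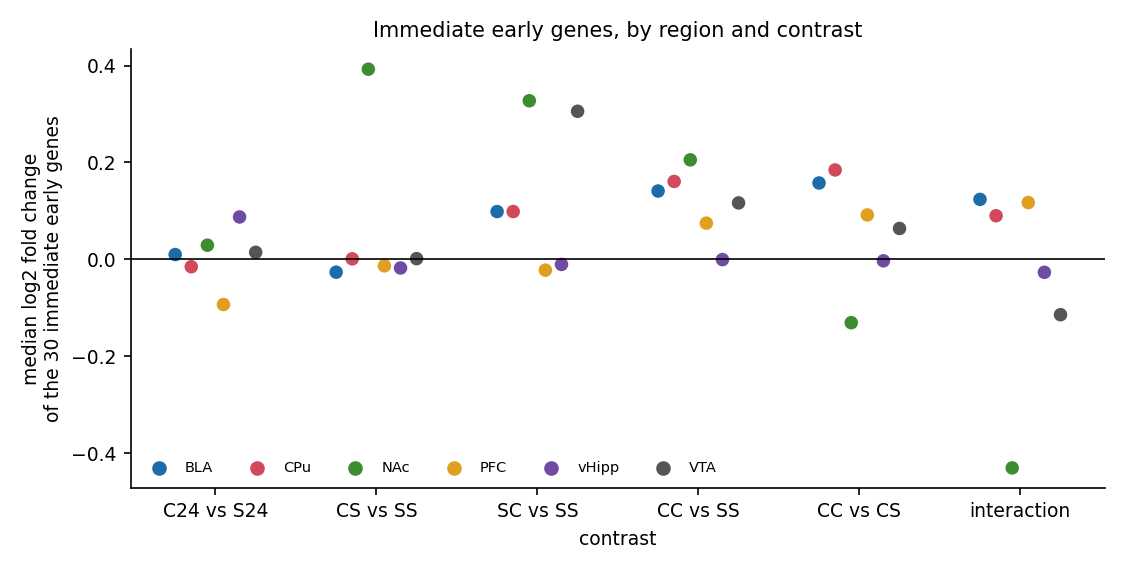
Median log2 fold change of the 30 immediate early genes, by contrast; each point is 1 region. The NAc had the highest median in CS against SS (0.39) and the lowest in the interaction (-0.43); without the NAc libraries that stood apart these were 0.13 and -0.16.

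The combined effect of cocaine history and cocaine injection was measured in CC against SS. Over the 6 regions 6 genes rose in the limma fit and 0 fell, and each was higher in 6 of 6 regions. Adamts1, a secreted metalloprotease gene, rose by 0.54 (SE 0.099, adjusted p = 0.00246), from 14.9 ± 2.26 CPM in SS (n = 8 mice) to 21.3 ± 9.32 CPM in CC (n = 7 mice). Gem, which encodes a small GTPase that inhibits calcium channels, rose by 0.58 (SE 0.11, adjusted p = 0.00437), from 2.52 ± 0.567 to 3.70 ± 0.420 CPM. Arid5a, which encodes an RNA-binding protein that stabilises Il6 messenger RNA, rose by 0.25 (SE 0.049, adjusted p = 0.00437), C1s1, a complement protease gene, by 0.76 (SE 0.15, adjusted p = 0.00437) and Bst1 by 1.05 (SE 0.21, adjusted p = 0.00720). C1s1 is uncertain, with 47.6% of its sequence in other genes. The sixth gene, Sik1, which encodes a kinase induced by cyclic AMP, was named after its values were seen and rose by 0.25 (SE 0.053, adjusted p = 0.00944). Mouse-115 had 41.9 CPM of Adamts1, against 15.7 to 21.9 CPM in the other 6 CC mice, and without it Adamts1 was at 0.34 (adjusted p = 0.319). The other 5 genes each lost the call without at least 1 mouse. With 1 mean per mouse limma called 0 genes (1472 at an unadjusted p under 0.05), and the count of 6 was 3 without mouse-012 and 3 without mouse-085. Fos averaged 0.31 (SE 0.096, adjusted p = 0.450) and passed only with sample quality weights (0.39, adjusted p = 0.0283), and Arc, Egr1, Npas4 and Fkbp5 averaged 0.07, 0.06, -0.02 and 0.04.

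Immediate early genes were higher in CC than in SS in 5 regions by camera, with medians of 0.21 in the NAc, 0.16 in the CPu and 0.14 in the BLA (adjusted p = 0.744 with an estimated correlation). In the CPu 4 of them, Fosb, Sik1, Nr4a3 and Fosl2, passed adjusted over the list alone. Blood cell markers were higher in the BLA, CPu, NAc and PFC, with medians of 1.89, 1.28, 1.35 and 1.33 and 6, 5, 5 and 7 members adjusted over the list alone (smallest adjusted p = 0.695 with an estimated correlation). Their scores were 2.24 in mouse-012 and 1.55 in mouse-115, against -0.66 to 0.04 in the other 5 CC mice and -0.71 to 0.15 in the SS mice. Oligodendrocyte markers were lower in 4 regions, by a median of -0.43 in the PFC (adjusted p = 0.744 with an estimated correlation). Cytosolic ribosomal protein genes were higher in the BLA by 0.30 and in the NAc by 0.10 and lower in 4 regions; without the BLA libraries that stood apart their median there was -0.00. In single regions edgeR called 0 genes in CC against SS, with 202 to 962 at an unadjusted p under 0.05; DESeq2 called 2 in the CPu and 1 in the BLA, and limma voom 0. The gene with the smallest p was Ccn1 in the BLA (log2 fold change 0.64, adjusted p = 0.339), Cwc25 in the CPu (0.25, adjusted p = 0.194), Des in the NAc (0.57), Cyp2u1 in the PFC (-0.31), Psmg4 in the vHipp (-0.68) and Fah in the VTA (-0.22). Over all genes 0 list members were called, against 43 adjusted over the list alone.

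Whether a cocaine injection changed expression in mice with a cocaine history was asked by CC against CS. No gene was called over the 6 regions, with 427 at an unadjusted p under 0.05 in the limma fit and 0 with 1 mean per mouse (438). Fos averaged 0.14 (SE 0.10), Arc -0.03, Egr1 -0.01, Npas4 -0.13 and Fkbp5 -0.05. Without mouse-014 limma called 11 genes, without mouse-115 20, and with sample quality weights 18. In single regions edgeR, DESeq2 and limma voom called 0 genes, with 231 to 746 at an unadjusted p under 0.05 in edgeR; without VTA-072 or without VTA-091 it called Hcrt alone in the VTA. The gene with the smallest p was Gypc in the BLA (log2 fold change 1.06), Gm11410 in the CPu (-4.33), Gm37939 in the NAc (-0.64), Gm26984 in the PFC (0.90), Col9a1 in the vHipp (1.49) and Hcrt in the VTA (-6.23, adjusted p = 0.558). Immediate early genes were higher in the CPu, BLA, PFC and VTA, by medians of 0.18, 0.16, 0.09 and 0.06, and lower in the NAc by -0.13 (adjusted p = 0.935 with an estimated correlation). Heat shock and protein folding genes were lower in the PFC, NAc and CPu, by medians of -0.22, -0.21 and -0.13 (adjusted p = 0.935 with an estimated correlation); the difference of the mean scores was -0.19, or -0.12 without mouse-012 or mouse-151 and -0.29 without mouse-115. Medium spiny neuron genes were lower in the PFC by -0.57 (adjusted p = 0.935 with an estimated correlation), against 0.05 without the PFC libraries that stood apart. List members called numbered 0 over all genes and 8 adjusted over the list alone.

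The interaction asked whether the response to cocaine differed between mice with a cocaine and a saline history. Over the 6 regions 5 genes had a positive and 3 a negative interaction in the limma fit. The only one that was neither a pseudogene nor a predicted gene was Atp5j2 (-0.74, SE 0.15, adjusted p = 0.00354), with 38.8 ± 7.82 CPM in CC (n = 7 mice), 42.9 ± 6.28 in CS (n = 6), 65.4 ± 20.1 in SC (n = 8) and 38.5 ± 3.70 in SS (n = 8). Without the 21 libraries with Gm20594 counts limma called 0 genes (613 at an unadjusted p under 0.05), with 1 mean per mouse 1, and without mouse-065 14. Fos, Arc, Egr1, Npas4 and Fkbp5 had interactions of -0.04, -0.13, -0.14, -0.25 and -0.15, none past the test. In the CPu edgeR called Gm11410 (-10.77, SE 1.69, adjusted p = 0.00326), and in the other regions 0 genes, with 503 to 1919 at an unadjusted p under 0.05; DESeq2 called 4 in the vHipp, 3 in the VTA and 1 in the BLA, and limma voom 0. Without VTA-072 or without VTA-091 edgeR called Hcrt in the VTA. Immediate early genes had a negative interaction in the NAc, with 0 of 30 positive and a median of -0.43, and a positive one in the PFC, with 0.12 (adjusted p = 0.819 with an estimated correlation); without the NAc libraries that stood apart the NAc median was -0.16. Excitatory neuron markers had negative interactions in the NAc and the CPu (-1.46 and -0.75), the latter with 6 members adjusted over the list alone (adjusted p = 0.819 with an estimated correlation). These were -0.34 and -0.17 without the libraries that stood apart, among them NAc-151 and CPu-151 of CS, which were high in these markers. Over all genes 0 list members were called, against 29 adjusted over the list alone.

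Differences between the regions came mostly from the vHipp. The limma F test called 5 genes in CS against SS, 5 in SC against SS and 8 in the interaction, all named after their values were seen. In CS against SS the serotonin receptor gene Htr2c had a log2 fold change of 2.01 in the vHipp (SE 0.55, adjusted p of the F test 0.0236) and -0.09 to 0.31 elsewhere, Tll2 2.26 and Cyth4 -0.78; choroid plexus and ependymal markers had a median of 5.63 there, and 0.79 without the libraries that stood apart. In SC against SS the kinase gene Plk5 had -1.45 in the vHipp (SE 0.61, adjusted p of the F test 0.00624), and Pdyn, which encodes the precursor of dynorphin, -1.51 in the vHipp and 1.77 in the VTA, where medium spiny neuron genes had a median of 0.75, and 0.05 without the libraries that stood apart. In the interaction Plk5 had 2.06 and Htr2c -2.63 in the vHipp, where choroid plexus and ependymal markers had a median of -5.69 with 11 of 12 adjusted over the list alone (adjusted p = 0.819 with an estimated correlation), and -2.76 without the libraries that stood apart. In SC against SS their vHipp median was 5.30. Leaving out 1 mouse moved the count in CS against SS to 48 without mouse-072, 15 without mouse-073, 9 without mouse-122, 1 without mouse-091 and 0 without mouse-014, mouse-035, mouse-052, mouse-055, mouse-094, mouse-151 or mouse-162. In SC against SS it was 51 without mouse-125, 9 without mouse-073 or mouse-161, 2 without mouse-011, mouse-043 or mouse-094, 1 without mouse-035 and 0 without mouse-052, mouse-065, mouse-105 or mouse-113. In the interaction it was 71 without mouse-125, 68 without mouse-072, 66 without mouse-053, 21 without mouse-083, 18 without mouse-073, 15 without mouse-122, 5 without mouse-012 and 2 without mouse-052. It was 1 there without mouse-031, mouse-035, mouse-043, mouse-055, mouse-065, mouse-074, mouse-094, mouse-105, mouse-113 or mouse-151, and 0 without mouse-014. CC against CS had 0 such genes with all mice, 3 without mouse-091 and 1 without mouse-145.

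**Figure D4:**
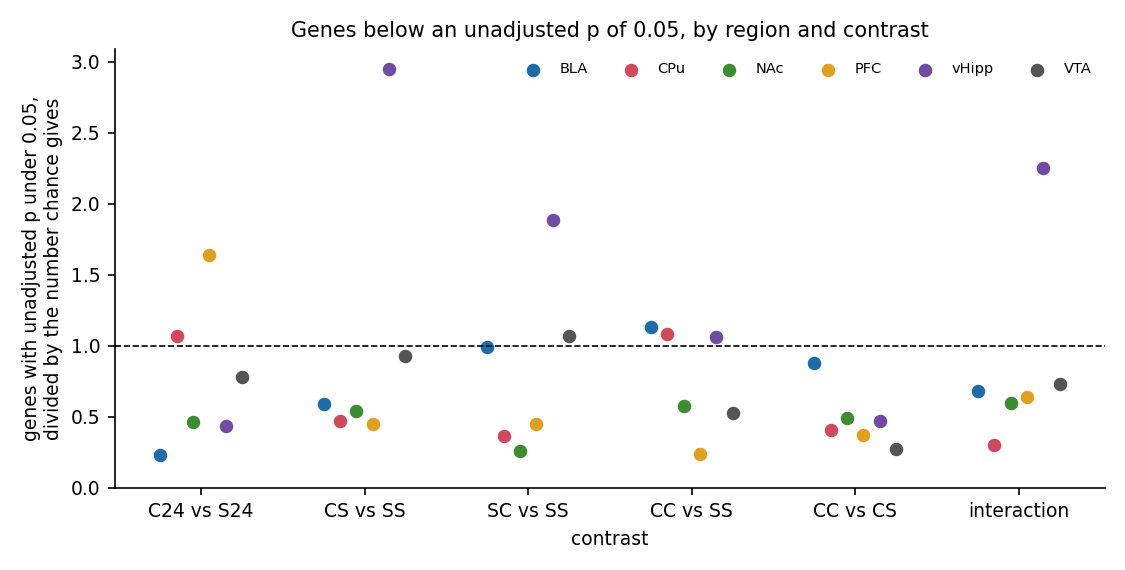
Number of genes with an unadjusted p under 0.05 in edgeR divided by the number chance gives, by contrast; each point is 1 region and the dashed line marks a ratio of 1. The vHipp reached 2.95 in CS against SS, 1.89 in SC against SS and 2.25 in the interaction.

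Fold changes were compared across genes between contrasts that shared no library; genes are not independent replicates, so no p is given. The effects of cocaine after saline and after cocaine (SC against SS with CC against CS) had Pearson's r across genes of 0.12 in the BLA, -0.06 in the CPu, -0.25 in the NAc, -0.14 in the PFC, -0.47 in the vHipp and -0.15 in the VTA. The effects of cocaine history at 24 h and at 30 d (C24 against S24 with CS against SS) had r of 0.02 in the BLA, 0.07 in the CPu, -0.04 in the NAc, 0.19 in the PFC, -0.67 in the vHipp and -0.03 in the VTA. Choroid plexus and ependymal markers moved in opposite directions in the vHipp in both pairs, with medians of -4.36 in C24 against S24 and 5.63 in CS against SS, and of 5.30 in SC against SS and -0.81 in CC against CS, the last not called by camera (adjusted p = 0.333). Libraries vHipp-182 of S24, vHipp-055 of CS, vHipp-043 of SC and vHipp-053 of CC stood apart as high in them. Among the genes above the median expression the latter values were -0.17, 0.22, -0.38, -0.03, -0.68 and 0.03.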

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

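Chosen only after their results were seen were the tests of a minority of the C24 mice, of vessel and microglia markers, of depth, of the 3 accounts of the Gm20594 counts, of midbrain tissue in NAc-083, the splits for the NAc in SC against SS, all tests of SS against S24, 1 mean per mouse, exact permutation of list means, and the fits and list scores without single mice, without the libraries that stood apart or without the libraries with Gm20594 counts.

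A set of 155 genes, Gbp4 and Tnfsf10 among them, was higher in C24 than in S24 over the 6 regions. Of the 8 C24 mice, 4 lay above every S24 mouse in the mean over these genes, at the limit set for a rise in a minority of the C24 mice. That count rests on mouse-191 of S24 (0.217), since the next S24 mouse, mouse-225, had 0.017. All 8 C24 mice (lowest -0.166) lay above the S24 mean of -0.175 (SD 0.235). The genes were chosen as higher in C24 in these same mice, which favours such an order. It therefore cannot decide whether all C24 mice rose. The 155 genes higher and 6 lower became 51 genes in all without mouse-203 and 270 without mouse-195, which is what a rise in a few mice predicts. They became 83 without mouse-204 of S24, so low S24 mice carry part of the pattern. The median log2 change was 0.16 for vessel and 0.13 for microglia markers, and their upper quartile 0.20 and 0.15. All lay below the 25th percentile of 0.26 of the 155 genes. Those genes were picked by their change in this same contrast, so the comparison cannot decide whether more vessel tissue or more microglia is the whole account. Of these markers 13 of 13 and 12 of 12 had positive values, and 3 and 2 of them were themselves called. Deeper sequencing is argued against by a ratio of 1.02 between the mean total counts of C24 and S24, and other splits of the 16 mice called up to 419 genes, so chance could not be excluded; the block understates the errors of genes that vary between mice (SE of Gbp4 0.24, and 0.43 with 1 mean per mouse), and a further structure of the mice was not tested. A response to cocaine in some mice and an immune event in some mice both stay open, as untested.

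Counts at Gm20594 and Gm11410 marked 21 libraries, 19 of SC and 2 of CS, with a median total of 27.3e6 counts against 22.8e6 in the others. A fixed property of the mice is argued against as the whole account by 5 mice with libraries of both kinds, although 4 mice had libraries of this kind alone, and a response to a cocaine challenge in any history by 0 CC libraries with the counts. Another alignment or library preparation of these libraries is a candidate explanation: of the 55 genes lower in them within their group, 29.1% were pseudogenes, against 2.71% of all genes tested (Fisher's exact p = 7.34e-13, with genes that are not independent). Of the 90 genes higher in them, 4.44% were pseudogenes (Fisher's exact p = 0.311). No label records such a difference. A response to a first cocaine injection is argued against for CPu-072 and vHipp-111 of CS, whose mice were injected with saline. They had 2.45 and 3.86 CPM of Gm20594, against at most 0.038 CPM in the 209 libraries without the counts. For the 19 SC libraries such a response is argued against as the whole account. All 37 SC libraries came from injected mice, and those without the counts had at most 0.038 CPM. Mouse-065 had 3.13 CPM in the vHipp and 0 CPM in the BLA, CPu, PFC and VTA. Mouse-161 had 0 CPM in each of its libraries, although 4 mice had the counts in every library. A response limited to some regions of some SC mice was not tested. Without the 21 libraries 2 genes were called over the 6 regions in SC against SS in place of 21.

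Tissue from outside the region was weighed for the NAc and the vHipp. In NAc-083 Slc6a3 had 62.0 CPM, against at most 2.68 CPM in the other NAc libraries, and its excess over their median was 3.86% of the VTA level, beside 3.45% for Th, 3.10% for Ddc and 3.38% for Slc18a2, so midbrain tissue in that punch is a candidate source of the Slc6a3 call. The other NAc libraries expressed all 4 genes, at medians of 0.516, 12.6, 16.7 and 6.63 CPM for Slc6a3, Th, Ddc and Slc18a2. In the vHipp 2519 genes had an unadjusted p under 0.05 in CS against SS, and 2069 without the libraries that stood apart. The median of the choroid plexus and ependymal markers was still positive in that fit, as given above. The count therefore cannot decide whether choroid plexus tissue in some punches is the whole account. A change in the vHipp after cocaine stays open, as untested.

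Other splits of the same libraries or mice into groups of the same sizes were fitted for each count, with 100 splits per regional count and 40 for the others, the real one included. For the gene list calls of C24 against S24 the real count ranked first, with 67 calls against a median of 47 and at most 63 in the other splits. With 40 of 6435 possible splits drawn and so narrow a margin, this does not exclude chance. An estimated correlation, fry and exact permutation of list means each called 0 lists there, so chance stays open for any single list. It could not be excluded for the list calls of CS against SS (58, highest other 59), SC against SS (51 and 58), CC against SS (56 and 62), CC against CS (37 and 65) and the interaction (43 and 66). The other splits gave medians of 45, 44, 42, 48 and 47 list calls in the same order. For the genes called in single regions it could not be excluded in SC against SS in the BLA (1, highest other 2), the NAc (2 and 156) and the VTA (1 and 1), in C24 against S24 in the VTA (1 and 10) and in the interaction in the CPu (1 and 2). Over the 6 regions it could not be excluded in CS against SS (11 and 17), SC against SS (21 and 23), CC against SS (6 and over 100) and the interaction (8 and 273). The splits with 156, 10, over 100 and 273 genes called several times the real count, which points to a structure of the samples other than the conditions or, for the 6-region counts, to errors that the block understates; the structure was not tested. Counts as large as the real one came in 9 of 100 splits for C24 against S24 in the VTA, and in 32 and 29 of 40 for the list calls of CC against CS and the interaction. For the 31 regions and contrasts and the 4 results over the 6 regions with no gene called, any split gives at least 0 genes, so chance was not tested.

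A library stood apart where its gap to the nearest other, as a share of the range of its group, passed Dixon's 95% limit. This happened 41 times, in 36 libraries, over 315 combinations of a group and a measure, or 2.60 per 20, while chance gives about 1 in 20 groups. The fits without such libraries kept 6 of the 36, which stood apart in heat shock and protein folding genes alone: BLA-161, PFC-161, vHipp-161, BLA-182, VTA-182 and VTA-115. For total count the shares were 0.604 for BLA-205 in S24, 0.588 for CPu-182 in S24 and 0.729 for vHipp-125 in SC at the low end, and 0.705 for CPu-072 in CS and 0.676 for NAc-185 in S24 at the high end. For pseudogene counts they were 0.629 for CPu-115 in CC (highest) and 0.633 for vHipp-162 in SS (lowest). Dopamine neuron genes were high in CPu-151 in CS (0.671), NAc-083 in SC (0.904), PFC-091 in CS (0.796) and vHipp-191 in S24 (0.878). Medium spiny neuron genes were high in VTA-053 in CC (0.906) and VTA-113 in SC (0.911) and low in vHipp-122 in SS (0.668), and excitatory neuron markers were high in CPu-151 (0.866) and NAc-151 (0.721), both in CS. Choroid plexus and ependymal markers were high in BLA-183 in C24 (0.651), BLA-125 in SC (0.766), vHipp-053 in CC (0.7997), vHipp-055 in CS (0.686), vHipp-182 in S24 (0.646) and vHipp-043 in SC (0.5681). Leptomeningeal fibroblast markers were high in CPu-161 in SC (0.761), PFC-182 in S24 (0.582), vHipp-053 in CC (0.812), VTA-175 in C24 (0.869) and VTA-065 in SC (0.817). Cytosolic ribosomal protein genes were high in BLA-115 in CC (0.844), CPu-011 in SS (0.617), NAc-014 in CS (0.905) and VTA-191 in S24 (0.741) and low in BLA-143 in SS (0.687). Heat shock and protein folding genes were high in BLA-115 (0.670) and VTA-115 (0.852) in CC and in BLA-182 (0.636), CPu-182 (0.696) and VTA-182 (0.711) in S24. They were low in SC in BLA-161 (0.628), CPu-161 (0.686), PFC-161 (0.594) and vHipp-161 (0.686). Among single genes, Gbp9 stood apart in VTA-191 in S24 (0.663), Gm11410 in BLA-011 in SS (0.629, 0.513 against 0.260 CPM in the nearest other) and in CPu-072 in CS (0.995, 38.0 against 0.408 CPM), and Slc6a3 in NAc-083 in SC (0.992, 62.0 against 0.840 CPM).

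The limma F test found genes whose change differed between the 6 regions: 5 in CS against SS, 5 in SC against SS, 8 in the interaction and 1446 in SS against S24, a contrast added after the data were seen. In that contrast choroid plexus and ependymal markers had a median of -5.41 in the vHipp and 2.06 in the PFC, with 9 and 6 members adjusted over the list alone, and the vHipp median was -0.87 without the libraries that stood apart, where the F test called 3607 genes; how far tissue content enters these counts stays open. For SS against S24 the real count ranked first, with at most 3 genes in the other splits. With 40 of 6435 possible splits drawn, and 1623 genes in a split of SC against SS, this does not exclude chance. Nor could chance be excluded for CS against SS (highest other split 88), SC against SS (1623) or the interaction (15). The splits with 88 and 1623 genes also point to a structure of the samples, which was not tested.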

How the results depend on the processing

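The fits without single mice, without the libraries that stood apart, without the libraries with Gm20594 counts, with 1 mean per mouse and with exact permutation of list means, and all tests of SS against S24, were chosen only after the data were seen. The cause of the changes below was not tested, except where fewer libraries or genes were used by construction. Under DESeq2 size factors each count of genes stayed within 1.5 times its value with TMM.

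The mouse was the block of the fits over the 6 regions. With no replicate block 41 genes in place of 21 were called in SC against SS, and the change of 2 genes in place of 8 differed between regions in the interaction; it moved no other count over the 6 regions by more than 1.5 times.

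In single regions DESeq2 called 7 genes in the PFC and 1 in the NAc in C24 against S24, 2 in the VTA and 1 in the CPu in CS against SS, and 1 in the BLA and 2 in the CPu in CC against SS, where edgeR called 0. In SC against SS it called 2 in the BLA, 1 in the CPu, 1 in the NAc, 1 in the vHipp and 3 in the VTA (edgeR 1, 0, 2, 0 and 1), and in the interaction 1 in the BLA, 4 in the vHipp and 3 in the VTA (edgeR 0). Limma voom called 0 genes in the regions where edgeR called any: the VTA in C24 against S24, the BLA, NAc and VTA in SC against SS and the CPu in the interaction. With 2 surrogate variables the count was 0 in the VTA in C24 against S24, and 2 in the BLA and 1 in the NAc in SC against SS. With no filter on low counts it was 0 in the NAc and 1 in the PFC in SC against SS.

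Without the libraries that stood apart edgeR called 5 genes in the PFC and 0 in the VTA in C24 against S24, 1 in the CPu, 0 in the NAc and 1 in the PFC in SC against SS, and 0 in the CPu in the interaction. Without the libraries with Gm20594 counts it called 1 in the VTA in CS against SS, 0 in the NAc and 0 in the VTA in SC against SS, and 0 in the CPu in the interaction. Leaving out 1 library, in groups of up to 5, gave 0 to 2 genes in the VTA in CS against SS (2 without VTA-072 or VTA-091), 1 to 2 in the NAc (1 without NAc-083 or NAc-113) and 1 to 2 in the VTA (2 without VTA-065) in SC against SS, and 0 to 1 in the VTA in CC against CS and in the interaction (1 without VTA-072 or VTA-091).

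For the genes called over the 6 regions, 1 mean per mouse gave 0 in C24 against S24 (155 higher and 6 lower with the mouse as a block), 0 in CS against SS (11), 0 in CC against SS (6) and 1 in the interaction (8). Sample quality weights gave 19 in CS against SS, 81 in SC against SS (21), 11 in CC against SS, 18 in CC against CS (0) and 23 in the interaction. With no filter on low counts SC against SS had 33. Without the libraries that stood apart there were 0 in CS against SS, 51 in SC against SS and 5 in the interaction, and without the libraries with Gm20594 counts 2 in SC against SS and 0 in the interaction. Without 1 mouse the counts ran from 51 (mouse-203) to 270 (mouse-195) in C24 against S24, 0 (mouse-122) to 36 (mouse-014) in CS against SS, 15 to 35 (mouse-065) in SC against SS, 3 (mouse-012, mouse-085) to 7 in CC against SS, 0 to 20 (mouse-115) in CC against CS and 6 to 14 (mouse-065) in the interaction.

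For the genes whose change differed between the regions, no filter on low counts gave 8 in CS against SS (5), 16 in SC against SS (5), 2 in CC against SS (0), 1 in CC against CS (0), 21 in the interaction (8) and 868 in SS against S24 (1446). Sample quality weights gave 8, 89, 2, 8, 262 and 5388 in the same order. Without the libraries that stood apart there were 2 in CS against SS, 30 in SC against SS, 76 in the interaction and 3607 in SS against S24, and without the libraries with Gm20594 counts 1 in SC against SS and 0 in the interaction. Without 1 mouse the counts ran from 0 to 48 (mouse-072) in CS against SS, 0 to 51 (mouse-125) in SC against SS, 0 to 3 (mouse-091) in CC against CS and 0 (mouse-014) to 71 (mouse-125) in the interaction.

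Gene list calls were 0 with an estimated correlation and with fry in all 6 planned contrasts, in place of 67 in C24 against S24, 58 in CS against SS, 51 in SC against SS, 56 in CC against SS, 37 in CC against CS and 43 in the interaction. Exact permutation of list means gave 0 in the first 5 of these and was not run for the interaction, which has no single exchange of labels. In SS against S24 the 48 calls became 7 with an estimated correlation, 27 with fry and 30 with 2 surrogate variables. Lists called in the opposite direction numbered 2 in C24 against S24 and 2 in CC against SS with 2 surrogate variables. Without the libraries that stood apart they numbered 3 in CS against SS, 1 in CC against SS, 2 in CC against CS and 1 in the interaction. Among the lists followed singly, oxidative phosphorylation subunits were called so with 2 surrogate variables in the BLA in CC against SS (adjusted p = 0.00204). Without the libraries that stood apart this held in the NAc in CS against SS (adjusted p = 2.42e-06), the BLA in CC against SS (1.07e-08) and CC against CS (0.00341) and the NAc in the interaction (1.17e-06), as were cytosolic ribosomal proteins in the NAc in CS against SS (1.00e-10).

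Without 1 mouse the difference of mean list scores moved furthest from 0.17 to 0.11 for endothelial and pericyte markers (mouse-203) and from 0.14 to 0.09 for microglia markers (mouse-205) in C24 against S24. It moved from 0.09 to 0.05 for immediate early genes in CS against SS (mouse-151), from 0.07 to 0.10 in CC against CS (mouse-151) and from -0.05 to -0.02 in the interaction (mouse-151). Oligodendrocyte markers in CC against SS moved from -0.19 to -0.12 (mouse-094).

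Among genes above the median expression, r across genes of C24 against S24 with CS against SS moved from 0.02 to -0.17 in the BLA, 0.07 to 0.22 in the CPu, -0.04 to -0.38 in the NAc and 0.19 to -0.0258 in the PFC. For SC against SS with CC against CS it moved from -0.06 to 0.0758 in the CPu, -0.25 to -0.41 in the NAc and -0.47 to -0.62 in the vHipp. The other 5 values of r moved by at most 0.1. The mean region marker levels in the report stayed within 1 SD when medians replaced means.

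No named gene past the test turned its direction under the alternatives run for it. Among genes not past it, Npas4 in CC against SS was -0.02 and 0.07 with sample quality weights (SE 0.11), and Fkbp5 there, Arc and Egr1 in CC against CS and Fos in the interaction also changed sign under some alternative, with values below 1 SE. Fos in CC against SS passed the test with sample quality weights (0.39, adjusted p = 0.0283). Without mouse-115 Adamts1 in CC against SS lost its call (0.34, adjusted p = 0.319). In single regions 107 comparisons with an alternative kept their side of the threshold, 3 gained a call and 15 lost it, and over the 6 regions 210 kept it, 1 gained a call and 19 lost it. Depth limited the tests to the 16609 to 17105 genes per region that passed the filter on low counts, and changes of the other genes were not tested in single regions. In the simulated NAc contrast, whose changed genes all lay above a set mean count, 42% of those changed by 1.3 times were called.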

Other observations

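The contrast of SS against S24 and its tests were chosen only after the data were seen; the other splits were drawn after the counts were known.

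Mice with a saline history differed between 30 d of withdrawal, 1 h after a saline injection (SS), and 24 h of withdrawal with no injection (S24). In the limma fit 2841 genes rose and 3133 fell in SS over the 6 regions. The 5 genes with the smallest p were Zbtb40, Hspa5, Fosb, Pdia4 and Xbp1. Zbtb40 rose by a log2 fold change of 0.95 (SE 0.054, adjusted p = 1.56e-38). Hspa5, which encodes the chaperone BiP, rose by 0.99 (SE 0.062, adjusted p = 1.12e-33), Pdia4, a disulfide isomerase gene, by 0.95 (SE 0.064, adjusted p = 9.16e-31) and Xbp1, a transcription factor gene of the unfolded protein response, by 0.64 (SE 0.043, adjusted p = 2.60e-30). Fosb rose by 1.24 (SE 0.083, adjusted p = 9.16e-31) and Fos, named like Cirbp after its values were seen, by 1.45 (SE 0.11, adjusted p = 1.49e-27). Cirbp, which encodes a cold-inducible RNA-binding protein, fell by 0.81 (SE 0.060, adjusted p = 5.54e-27) and was lower in 6 of 6 regions. The mean Fos level over mice was 15.9 ± 6.41 CPM in S24 and 18.0 ± 5.33 CPM in C24 (SD, n = 8 each), against 43.7 ± 11.3 CPM in SS and 47.3 ± 7.90 CPM in SC (n = 8 each), 46.4 ± 9.18 CPM in CS (n = 6) and 53.01 ± 7.11 CPM in CC (n = 7).

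Among the fixed lists, immediate early genes were higher in SS in 6 of 6 regions by camera. Their median log2 fold change was 0.91 in the PFC (30 of 30 positive, 25 called over all genes, adjusted p = 3.73e-05 with an estimated correlation), 0.71 in the CPu (0.00812), 0.63 in the BLA (0.0144) and 0.61 in the vHipp (0.000901). It was 0.42 in the NAc and 0.28 in the VTA, where the call was lost with an estimated correlation (adjusted p = 0.159 and 0.221). Heat shock and protein folding genes were higher in 6 of 6 regions as well, with medians of 0.58 in the VTA (20 of 20 positive, adjusted p = 0.00216 with an estimated correlation), 0.67 in the PFC (0.00396) and 0.62 in the NAc (0.00766). Their medians of 0.75 in the CPu, 0.73 in the BLA and 0.55 in the vHipp had an adjusted p of 0.0584, 0.0990 and 0.0992 with an estimated correlation. Withdrawal time, handling, injection and any difference between the cohorts change together in this contrast and cannot be told apart.

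The count of 5974 genes called in SS against S24 ranked first among the 40 splits drawn of 6435 possible, with at most 1879 in the others. So few splits cannot fully exclude chance. With 1 mean per mouse limma called 5987 genes. Chance could not be excluded for the 48 list calls at the preset correlation (highest other split 63).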
